A study of Mus musculus with 20 samples.

How the data were processed

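RNA was measured in 20 libraries of immortalised primary murine cancer-associated fibroblasts (CAFs), 5 in each of 4 groups. Cells were kept for 32 h in 0.2 mM glutamine with 25 uM EIPA or with the DMSO vehicle. Others were kept as long in 4 mM glutamine with the DMSO vehicle, with or without IL-1a at 25 pg/mL. EIPA is an amiloride analogue that inhibits sodium-proton exchange and is used to block macropinocytosis, the bulk uptake of extracellular fluid. The treatment protocol gives 25 mM EIPA where the sample titles give 25 uM, and the value of the titles is used in the text. The labels do not say whether the 5 replicates of a group were separate cultures, so the p-values measure only the spread between these samples.

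RNA was extracted with the PureLink RNA Mini Kit, libraries of polyadenylated RNA were made with a Watchmaker mRNA kit and xGEN adaptors, and an Element AVITI gave reads of 75 bases from both ends. The submitters' processing notes name RSEM and mm10, without versions. The aligner and the annotation release are not given in the sources used here. The deposited values are TPM, transcript abundances scaled to a fixed total, from the authors, with 2 decimals, for 32285 genes in 20 libraries. Every library summed to between 999999.47 and 1000000.8 TPM, so the table keeps no trace of sequencing depth: the depth per library is unknown, no counting interval could be given, and genes of a few TPM could rest on few reads. An exact 0 is described as listed at 0.

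Gene positions and symbols were checked against the GENCODE M21 annotation of GRCm38 (mm10), which held 32158 of the 32285 IDs, 31436 of them under the same symbol. Another 38 symbols stood for more than 1 ID. Positions are counted from 1. Genes with at least 1 TPM in at least 5 libraries were tested (12350 genes), and 11398 genes were listed at 0 in all 20 libraries.

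Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a single model of the 4 groups over the 20 libraries and an intensity trend in the variance. The model gave 3 comparisons, EIPA against vehicle at 0.2 mM glutamine, IL-1a against vehicle at 4 mM glutamine, and 0.2 mM against 4 mM glutamine in vehicle, and a test of the difference between the EIPA and IL-1a responses. The p-values were adjusted by Benjamini-Hochberg over the 12350 genes of each comparison and called under 0.05. A gene is said to rise, fall or change only when it was called. Log2 fold changes carry their SE after ±, TPM values their SD, with n = 5 libraries per group. The added 1 TPM makes the fold changes of genes of low level smaller than their ratios of TPM.

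Gene lists, comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The 37 lists had 917 entries, 914 of them in the table, and overlap in part. They covered markers of inflammatory (iCAF), myofibroblastic (myCAF) and antigen-presenting (apCAF) CAFs, pan-fibroblast genes, signalling targets, matrix, metabolism, stress responses and other cell types. Lists with at least 5 tested members were tested, which left 34. The leukocyte list had 3 tested members, the mural list 2 and the Schwann cell list 2, and they are given as levels. Lists were tested against all other tested genes with camera at a preset correlation of 0.01 between genes, adjusted over the 34 lists of each comparison. Camera with an estimated correlation and fry, which asks whether the members move to either side on balance without comparing them with other genes, were run as alternatives. Member counts are given over all genes tested. Where the counts adjusted over the list alone differ, they follow, and otherwise they were equal.

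The iCAF and myCAF scores, means of log2(TPM + 1) over the tested members (23 and 28 genes), and the share of TPM from mitochondrially encoded mRNAs were compared by two-sided exact permutation of 252 assignments, of which 0.0079 is the smallest p possible. Named genes were the 6 called genes with the largest change in each direction among those with a mean of at least 5 TPM in the higher group and no overlap between the groups, a panel of 15 CAF genes, and 2 members of each of the 5 lists with the smallest camera p. Some of the genes these rules pick are not reported here. Other members named as examples of a list were chosen after their values were seen. Reads of gene families with near-identical members (Prl2c2, Mt1 and Mt2, Scd2, H2 genes and histone genes) can be shared between members, so their levels are uncertain.

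The median gene was higher by 0.14 (log2) at 0.2 mM than at 4 mM glutamine, against 0.02 for EIPA and 0.01 for IL-1a. Changes between the glutamine levels are therefore given relative to the median gene, while their calls are those of the unshifted values. Where median-of-ratios scaling gave other member counts for EIPA or between the glutamine levels, these follow, higher before lower.

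The alternatives were a pseudocount of 0.1, no filter (20887 genes), a mean of at least 5 TPM (10041 genes), median-of-ratios scaling, quantile normalisation, the replicate number as a block, only the groups compared, each of the 10 libraries of a comparison left out in turn, no variance trend, an absolute log2 fold change of at least 1, the other list tests and a median in place of a mean over a list. Chosen after seeing the data were the mitochondrially encoded genes left out, 3 libraries left out and a residual component as a covariate. Each comparison was repeated on 100 splits of its libraries, the real one included.

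The workflow was tested on simulated data with 200 changed genes per comparison. Genes changed by 0.5 (log2) were called in 60 of 67 cases for EIPA, 57 of 67 for IL-1a and 62 of 67 for glutamine, and genes changed by 1 in 67 of 67 cases for each of the 3. Of the unchanged genes, 6 of 12112, 9 of 12150 and 6 of 12150 were called. The changed genes were drawn among genes of at least 5 TPM in no list, so genes of lower level were not covered. A list shifted by 0.5 was called by camera with either correlation and by fry, with 0 of the 33 other lists called. The simulated genes varied independently of each other, so false calls of lists with correlated members could not be seen. The exact test of list scores gave p under 0.05 in 16 of 400 draws without a change. Lists and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.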

Results

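Transcript levels were collected from 20 libraries of cultured murine CAFs, the fibroblasts of the tumour stroma, with 5 libraries in each of 4 groups: 0.2 mM glutamine with EIPA, 0.2 mM glutamine with vehicle, 4 mM glutamine with IL-1a and 4 mM glutamine with vehicle. Between 11749 and 12045 genes reached 1 TPM per library. The first principal component held 70.0% of the variance and set the 0.2 mM from the 4 mM libraries, and the second held 12.6% and set EIPA from vehicle at 0.2 mM. The third, with 4.07%, set 3 libraries of the 4 mM groups apart, IL-1a replicates 1 and 5 and vehicle replicate 5. There Ccn1, a YAP target that encodes a matrix-associated protein, was at 201, 235 and 231 TPM against 379 to 599 in the other 7 libraries of these groups, and Dcn, the proteoglycan decorin, at 380, 371 and 398 TPM against 120 to 263. Markers of most other cell types were near 0, with means over the 20 libraries of 0.0005 TPM for Ptprc (leukocytes), 0.103 for Epcam (epithelium), 0.0775 for Pecam1 (endothelium), 0.096 for Rgs5 (mural cells) and 0 for Sox10 (Schwann cells). The highest members of the lists too small for a test were Cd14 (13.5 TPM) among leukocyte genes, Mcam (7.78) among mural genes and Mbp (31.4) among Schwann cell genes. Mesothelial markers were expressed, 11 of 12 passing the filter, with Msln at 89.2 and Krt19 at 176 TPM.

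Mitochondrially encoded mRNAs, which encode subunits of the respiratory chain and ATP synthase, took 5.69% ± 0.63 of TPM (SD, n = 5) with EIPA and 8.87% ± 0.28 with vehicle at 0.2 mM glutamine. They took 10.0% ± 0.51 with IL-1a and 10.4% ± 1.17 with vehicle at 4 mM. The share was lower by 3.18 points with EIPA (a difference of -3.18, exact permutation p = 0.0079, the smallest possible, adjusted over 3 comparisons p = 0.012). It was also lower at 0.2 mM than at 4 mM glutamine (difference -1.50, exact permutation p = 0.0079). The vehicle libraries reached 9.24% at 0.2 mM and went from 9.30% to 12.3% at 4 mM, where replicate 3 was highest. With IL-1a the share differed by -0.37 (exact permutation p = 0.63).

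EIPA was compared with vehicle at 0.2 mM glutamine to ask what a block of macropinocytosis does to CAFs and their subtype markers under glutamine shortage. Insig1, a sterol sensor, was at 293 ± 32.7 TPM (SD, n = 5) with EIPA and at 17.7 ± 0.957 TPM (n = 5) with vehicle, a log2 fold change of 3.97 ± 0.10 (SE; limma adjusted p = 3.4e-17). Acta2, the smooth muscle actin that marks myofibroblastic CAFs, was at 108 ± 30.3 and 533 ± 131 TPM, a change of -2.31 ± 0.21 (limma adjusted p = 1.5e-08). Tagln, an actin-binding protein of contractile cells, moved with it, from 295 ± 69.7 to 51.6 ± 15.6 TPM (-2.53 ± 0.22, limma adjusted p = 1.0e-08). Ccl2, a chemokine that attracts monocytes, was at 31.8 ± 12.8 TPM with EIPA and 3.004 ± 0.759 with vehicle (2.97 ± 0.21, limma adjusted p = 4.5e-10). In mm10, Insig1 (ENSMUSG00000045294) lies on the plus strand of chromosome 5 from 28071363 to 28078662, Tagln (ENSMUSG00000032085) on the minus strand of chromosome 9 from 45929619 to 45936058, and Acta2 (ENSMUSG00000035783) on the minus strand of chromosome 19 from 34241090 to 34255590.

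In this comparison 5986 of 12350 genes were called by limma, 3383 higher and 2603 lower with EIPA, of which 237 and 152 changed at least 2-fold. The share of higher genes, 56.5%, was 49.5% under median-of-ratios scaling (2911 higher and 2971 lower), 48.5% under quantile normalisation and 47.0% with the mitochondrially encoded genes left out. The groups did not overlap in 4279 genes, where chance gives 0.79%. Among the genes that rose most, beside Insig1, were Prl2c2, a member of the prolactin family (4.29 ± 0.57), and Idi1, an isoprenoid enzyme (3.56 ± 0.09). Beside Tagln, the genes that fell most were Flrt3, an adhesion protein (-2.67 ± 0.19), the collagen cross-linking enzyme Loxl2 (-2.49 ± 0.11), Col3a1, a fibrillar collagen (-2.39 ± 0.18), and the guidance factors Sema3c (-2.36 ± 0.19) and Sema3d (-2.33 ± 0.16). Limma adjusted p for these 7 genes lay between 1.9e-17 and 3.3e-06. Insig1, Acta2, Tagln and 5 other genes are plotted by library.

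**Figure D1:**
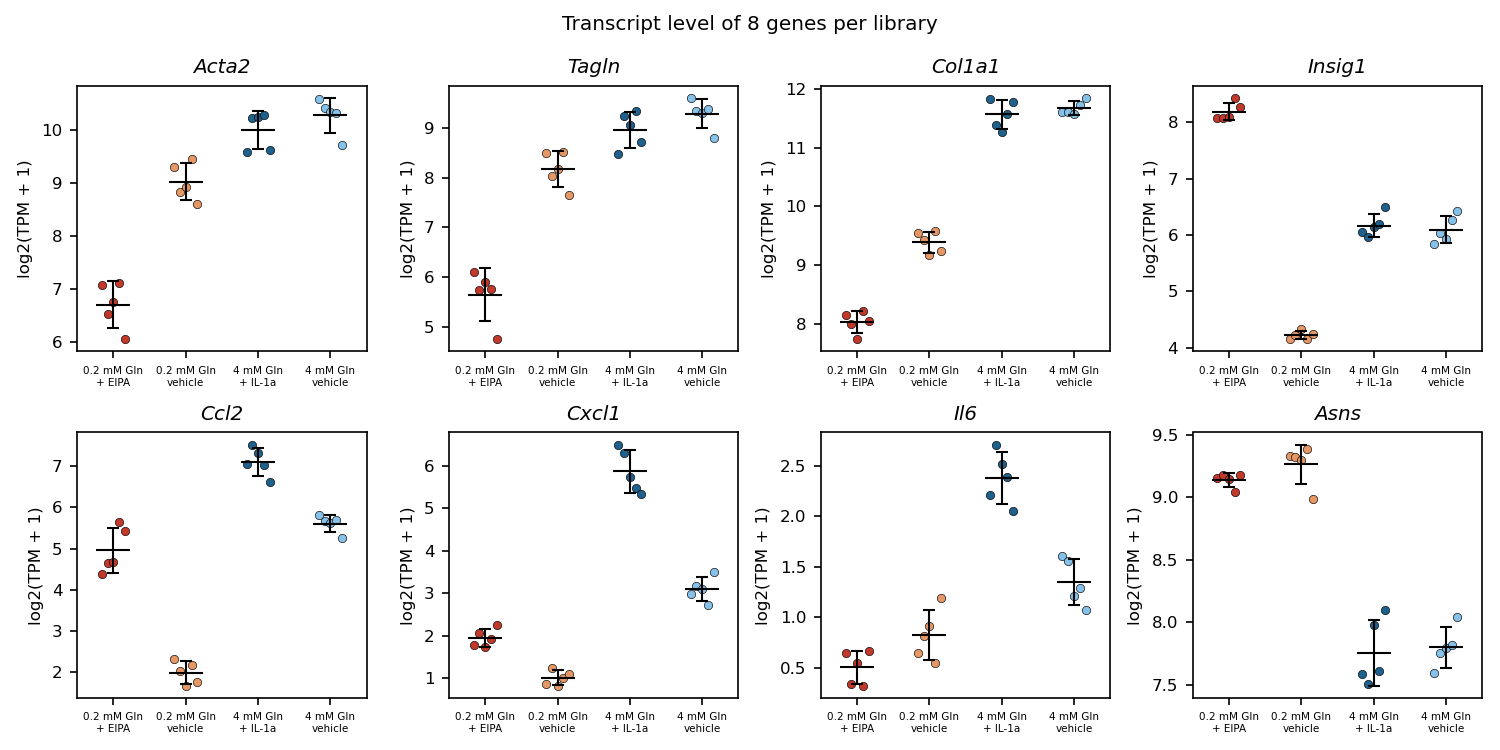
Level of 8 genes as log2(TPM + 1) in each of the 20 libraries, with points for libraries and bars for the mean ± SD of the 5 libraries of a group. Insig1 was at 293 TPM with EIPA and 17.7 TPM with vehicle at 0.2 mM glutamine, and Acta2 at 108 and 533 TPM.

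Of the fixed panel of CAF genes, Cxcl1, a chemokine for neutrophils (0.94 ± 0.18), Cxcl12, a chemokine of fibroblasts (0.33 ± 0.06), and Pdgfra, a growth factor receptor of inflammatory CAFs (1.14 ± 0.18), rose as Ccl2 did. Lif, a cytokine that signals through STAT3, fell (-0.84 ± 0.16). Il6, the main cytokine of inflammatory CAFs, was at 0.428 ± 0.161 TPM with EIPA and 0.794 ± 0.323 with vehicle (-0.32 ± 0.14, limma adjusted p = 0.071). It passed with a pseudocount of 0.1 (-0.75, adjusted p = 0.022) and without vehicle replicate 4 (-0.39, adjusted p = 0.039). Col1a1, the main chain of type I collagen (-1.36 ± 0.11), and Postn, a matrix protein of activated fibroblasts (-1.23 ± 0.12), fell. Dusp6, a feedback phosphatase of ERK (0.64 ± 0.17), rose, and Asns, asparagine synthetase, differed by -0.12 ± 0.10 (limma adjusted p = 0.34). The panel genes Has1 and Csf3 stayed below the filter, with group means of at most 0.126 TPM. Has1 was listed at 0 in all 10 libraries at 0.2 mM.

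Among the subtype lists, the 28 tested myCAF markers included the contractile genes Myl9 (-2.25 ± 0.19) and Cnn1 (-2.18 ± 0.28), which fell, and Cdh11, a cadherin (0.50 ± 0.15), which rose: 4 rose, 17 fell and 7 did not pass the test (4 rose and 18 fell adjusted over the list alone, 2 and 17 under median-of-ratios scaling) (median -0.64, camera adjusted p = 1.2e-05, and adjusted p = 0.089 with an estimated correlation). The 23 iCAF markers went both ways: 9 rose, 5 fell and 9 did not pass the test (8 and 5 under median-of-ratios scaling) (median 0.33, camera adjusted p = 0.52). Mt2, a metallothionein (3.19 ± 0.17), and Ccl7, a chemokine (1.39 ± 0.23), rose, and the matrix genes Ogn (-1.85 ± 0.20), Svep1 (-1.17 ± 0.07) and Dcn (-0.91 ± 0.33) fell. The iCAF score was 3.58 ± 0.16 with EIPA and 3.25 ± 0.06 with vehicle, a difference of 0.33, and the myCAF score 4.07 ± 0.17 and 4.77 ± 0.13, a difference of -0.70 (both exact permutation p = 0.0079, two-sided, the smallest possible, adjusted over 6 scores p = 0.0095). With a median in place of the mean over the list, the iCAF difference was -0.27 (exact permutation p = 0.079). Of the 8 apCAF markers, 3 rose, 3 fell and 2 did not pass the test (2 and 3 under median-of-ratios scaling) (median 0.12, mean 0.02, test direction down, camera adjusted p = 0.9). Members included the antiprotease Slpi (1.71 ± 0.23) and the uroplakin Upk3b (-1.75 ± 0.26). Of the 12 pan-fibroblast genes, 4 rose, 7 fell and 1 did not pass the test (median -0.73, camera adjusted p = 0.043, and adjusted p = 0.4 with an estimated correlation). Pdpn, podoplanin (1.07 ± 0.08), rose, and Col1a2 (-1.45 ± 0.16) and Sparc (-1.06 ± 0.08) fell. The call of this list was lost without EIPA replicate 3 or 5 or vehicle replicate 1 or 4 (camera adjusted p = 0.052 to 0.062), under median-of-ratios scaling (0.062) and quantile normalisation (0.071), and with the mitochondrially encoded genes left out (0.081).

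**Figure D2:**
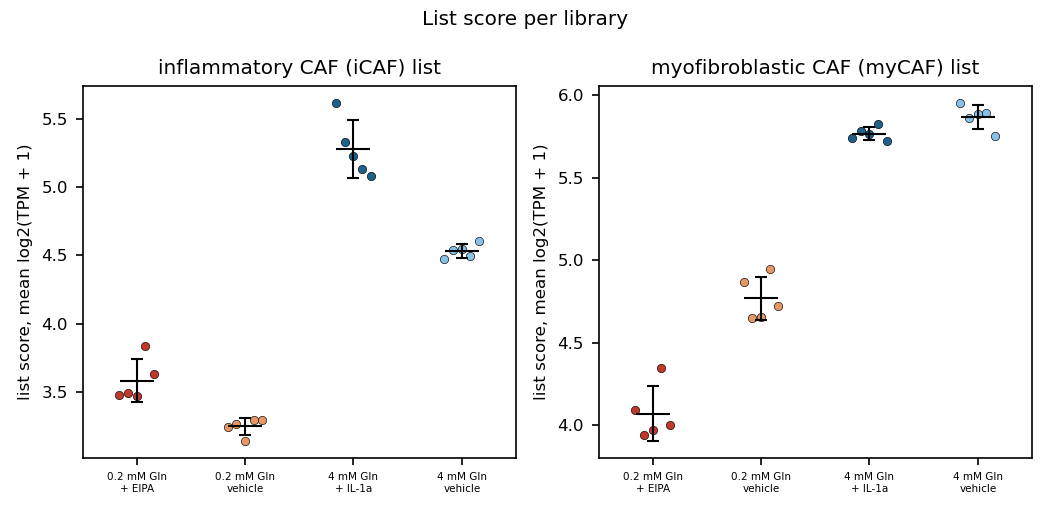
Scores of the iCAF list (23 genes) and of the myCAF list (28 genes), the mean log2(TPM + 1) over the members, in each of the 20 libraries, with the mean ± SD of the 5 libraries of a group. The myCAF score was 4.07 with EIPA and 4.77 with vehicle at 0.2 mM glutamine, and the iCAF score was 5.28 with IL-1a and 4.53 with vehicle at 4 mM.

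With EIPA, of the 21 collagens, 1 rose, 14 fell and 6 did not pass the test (median -0.67, camera adjusted p = 7.0e-07, and adjusted p = 0.089 with an estimated correlation). Col4a6 of basement membranes (-1.48 ± 0.13) fell, and Col7a1 of anchoring fibrils (1.06 ± 0.19) rose. Of the 33 matrix proteins and remodelling enzymes, 6 rose, 20 fell and 7 did not pass the test (median -0.58, camera adjusted p = 1.2e-05, and adjusted p = 0.2 with an estimated correlation). The cross-linking enzyme Lox (-1.30 ± 0.09) and the aggrecanase Adamts5 (-1.50 ± 0.10) fell, while the matrix metalloproteinases Mmp10 (2.70 ± 0.20), Mmp3 (2.51 ± 0.25) and Mmp13 (2.16 ± 0.25) rose. Of the 22 YAP and SRF targets, 2 rose, 14 fell and 6 did not pass the test (median -0.44, camera adjusted p = 3.8e-05, and adjusted p = 0.37 with an estimated correlation), among them Ccn2 (-1.42 ± 0.31) and the focal adhesion protein Zyx (-1.18 ± 0.10), while Amotl1 (0.76 ± 0.07) rose. Of the 23 TGF-beta targets, 6 rose, 9 fell and 8 did not pass the test (3 and 10 under median-of-ratios scaling) (median -0.19, camera adjusted p = 0.04, and adjusted p = 0.37 with an estimated correlation). Tgfb2, a TGF-beta ligand (-2.30 ± 0.12), and Tgfb1i1 (-1.52 ± 0.13) fell, and the cell cycle inhibitor Cdkn2b (0.85 ± 0.13) rose. The call of the TGF-beta list was lost without EIPA replicate 3 or 5 or vehicle replicate 1 (camera adjusted p = 0.053 to 0.062), under median-of-ratios scaling (0.061) and quantile normalisation (0.057), and with the mitochondrially encoded genes left out (0.057). Of the 11 mesothelial markers, 1 rose, 6 fell and 4 did not pass the test (1 rose and 7 fell adjusted over the list alone) (median -0.68, camera adjusted p = 0.011, and adjusted p = 0.45 with an estimated correlation), with Gpm6a, a membrane glycoprotein, at -1.79 ± 0.17.

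All 26 tested genes of cholesterol synthesis and uptake rose with EIPA, with a median of 2.18 (camera adjusted p = 7.6e-33, also past with an estimated correlation, adjusted p = 0.039). Of the 15 genes of fatty acid synthesis, 13 rose, 0 fell and 2 did not pass the test (median 1.32, camera adjusted p = 2.5e-09, and adjusted p = 0.089 with an estimated correlation). Scd2, a desaturase (2.82 ± 0.18), Elovl6, an elongase (2.41 ± 0.12), Fasn, fatty acid synthase (1.93 ± 0.09), and Acss2, which makes acetyl-CoA (1.75 ± 0.17), were among them. Of the 38 lysosome genes, 33 rose, 0 fell and 5 did not pass the test (34 rose and 0 fell adjusted over the list alone, 30 and 0 under median-of-ratios scaling) (median 0.40, camera adjusted p = 3.8e-13, and adjusted p = 0.096 with an estimated correlation), led by Gpnmb, a glycoprotein of stressed lysosomes (1.62 ± 0.12), Gla, a galactosidase (1.31 ± 0.09), and the cathepsins Ctsb (0.98 ± 0.07) and Ctsd (0.94 ± 0.06). Of the 31 genes of the macropinocytosis machinery and sodium-proton exchangers, 12 rose, 5 fell and 14 did not pass the test (12 rose and 7 fell adjusted over the list alone, 12 and 9 under median-of-ratios scaling) (median 0.12, camera adjusted p = 0.3). The exchanger Slc9a5 (0.57 ± 0.10) and the lipid kinase Pikfyve (0.47 ± 0.09) rose, and Anxa2, an annexin (-0.70 ± 0.07), fell. Of the 21 glycolysis genes, 17 rose, 1 fell and 3 did not pass the test (15 and 1 under median-of-ratios scaling) (median 0.42, camera adjusted p = 1.3e-05, also past with an estimated correlation, adjusted p = 0.039). Members included the lactate transporter Slc16a3 (1.15 ± 0.09) and the enzymes Aldoc (1.22 ± 0.24) and Pfkl (1.05 ± 0.11). Of the 23 hypoxia genes, 15 rose, 1 fell and 7 did not pass the test (14 and 1 under median-of-ratios scaling) (median 0.48, camera adjusted p = 2.9e-04, and adjusted p = 0.069 with an estimated correlation). Ankrd37 (1.44 ± 0.17) and the glucose transporter Slc2a1 (1.01 ± 0.11) rose, and Slc2a3, another (-0.75 ± 0.17), fell.

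All 13 mitochondrially encoded mRNAs fell (median -0.72, camera adjusted p = 1.1e-11, and adjusted p = 0.089 with an estimated correlation), the complex I subunits mt-Nd1 (-1.06 ± 0.07) and mt-Nd3 (-1.03 ± 0.09) most of all, in the libraries where these mRNAs took 5.69% of TPM. Of the 39 nuclear genes of oxidative phosphorylation, 8 rose, 16 fell and 15 did not pass the test (6 and 21 under median-of-ratios scaling) (median -0.10, camera adjusted p = 0.024, and adjusted p = 0.37 with an estimated correlation). Cycs, cytochrome c (-0.46 ± 0.07), fell, and Uqcrfs1 of complex III (0.31 ± 0.06) rose. Of the 24 NRF2 genes of the oxidative stress response, 23 rose, 0 fell and 1 did not pass the test (22 and 0 under median-of-ratios scaling) (median 0.59, camera adjusted p = 3.8e-13, and adjusted p = 0.069 with an estimated correlation). Beside Mt2 these included Mt1 (2.15 ± 0.14), Osgin1 (2.53 ± 0.15) and Pgd of the pentose phosphate pathway (1.34 ± 0.10). Of the 38 ATF4 genes of the amino acid response, 8 rose, 8 fell and 22 did not pass the test (8 rose and 7 fell adjusted over the list alone, 7 and 9 under median-of-ratios scaling) (median 0.07, mean 0.06, test direction down, camera adjusted p = 0.9). Ddit4, an inhibitor of mTORC1 (2.38 ± 0.20), rose, and Pycr1 of proline synthesis (-0.92 ± 0.14) fell. Of the 20 aminoacyl-tRNA synthetases, 3 rose, 7 fell and 10 did not pass the test (3 and 10 under median-of-ratios scaling) (median -0.11, camera adjusted p = 0.23). Members included Qars (0.66 ± 0.06) and Mars (-0.48 ± 0.08). Of the 22 genes of glutamine and glutamate metabolism, 5 rose, 4 fell and 13 did not pass the test (3 and 4 under median-of-ratios scaling) (camera adjusted p = 0.923). The cystine transporter Slc7a11 (0.75 ± 0.18) rose, and the amino acid transporter Slc7a5 (-0.50 ± 0.10) fell. Of the 22 genes of the unfolded protein response, 3 rose, 4 fell and 15 did not pass the test (camera adjusted p = 0.71). The chaperone Hspa5 (-0.57 ± 0.09) fell. With the mitochondrially encoded genes left out 1 member rose and 4 fell. The medians of the last pair of lists were within 0.01 of 0 and changed sign with the scaling.

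Of the 28 ERK targets, 17 rose, 2 fell and 9 did not pass the test (17 rose and 3 fell adjusted over the list alone) (median 0.49, camera adjusted p = 0.0012, and adjusted p = 0.41 with an estimated correlation). The transcription factors Etv4 (1.80 ± 0.21) and Etv5 (1.68 ± 0.17) and the cyclin Ccnd1 (1.29 ± 0.19) rose, and Myc (-0.59 ± 0.15) fell. Of the 34 NF-kB targets, 16 rose, 4 fell and 14 did not pass the test (16 rose and 5 fell adjusted over the list alone, 15 and 5 under median-of-ratios scaling) (median 0.28, camera adjusted p = 0.025, and adjusted p = 0.37 with an estimated correlation). Tnfaip2 (1.73 ± 0.17) and Ier3 (1.10 ± 0.13) rose, and Tnfaip3, an inhibitor of NF-kB (-0.80 ± 0.18), fell. Of the 14 chemokines, 6 rose, 0 fell and 8 did not pass the test (6 rose and 1 fell adjusted over the list alone, 6 and 1 under median-of-ratios scaling) (median 0.24, camera adjusted p = 0.024, and adjusted p = 0.37 with an estimated correlation), with Cxcl16 at 1.80 ± 0.11. Both calls were lost without EIPA replicate 5 (camera adjusted p = 0.062). Of the 21 JAK-STAT3 targets, 8 rose, 1 fell and 12 did not pass the test (6 rose and 1 fell adjusted over the list alone, 6 and 1 under median-of-ratios scaling) (median 0.18, camera adjusted p = 0.23). Under quantile normalisation 5 rose and 1 fell, and with the mitochondrially encoded genes left out 4 rose and 2 fell. Members included Junb (0.42 ± 0.13) and the receptor chain Il6st (-0.15 ± 0.05). Of the 12 genes of the IL-1 system, 5 rose, 0 fell and 7 did not pass the test (6 rose and 0 fell adjusted over the list alone) (median 0.27, camera adjusted p = 0.07). The IL-33 receptor Il1rl1 (1.91 ± 0.14) and Casp1 (0.69 ± 0.15) rose, and the list passed without the filter (camera adjusted p = 0.040). Of the 30 interferon-stimulated genes, 16 rose, 0 fell and 14 did not pass the test (16 rose and 1 fell adjusted over the list alone, 15 and 1 under median-of-ratios scaling) (median 0.69, camera adjusted p = 3.9e-04, and adjusted p = 0.56 with an estimated correlation). Members included Rtp4 (1.61 ± 0.33) and Stat2 (1.32 ± 0.13). Of the 18 angiogenic factors, 10 rose, 4 fell and 4 did not pass the test (11 rose and 5 fell adjusted over the list alone, 9 and 4 under median-of-ratios scaling) (median 0.37, camera adjusted p = 0.29). Angpt2 (1.69 ± 0.17) and Pgf (1.32 ± 0.17) rose, and Ptn (-1.43 ± 0.32) and Vegfd (-1.12 ± 0.10) fell.

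Of the 40 ribosomal protein genes, 26 rose, 3 fell and 11 did not pass the test (27 rose and 3 fell adjusted over the list alone, 19 and 3 under median-of-ratios scaling) (median 0.16, camera adjusted p = 6.9e-04, and adjusted p = 0.41 with an estimated correlation). Under quantile normalisation 15 rose and 3 fell (median 0.094). Members included Rps4x (0.47 ± 0.04) and Rps2 (-0.50 ± 0.04). Of the 40 cell cycle genes, 5 rose, 15 fell and 20 did not pass the test (4 and 17 under median-of-ratios scaling) (median -0.08, camera adjusted p = 0.046, and adjusted p = 0.37 with an estimated correlation). The ribonucleotide reductase genes Rrm1 (-0.84 ± 0.13) and Rrm2 (-0.51 ± 0.10) fell, and the checkpoint kinase Bub1b (0.43 ± 0.05) rose. The cell cycle call was lost without EIPA replicate 3, 4 or 5 or vehicle replicate 1, 2 or 3 (camera adjusted p = 0.053 to 0.082) and under quantile normalisation (0.063). Of the 20 p53 targets, 6 rose, 3 fell and 11 did not pass the test (5 and 3 under median-of-ratios scaling) (median 0.07, camera adjusted p = 0.73). Trp53inp1 (0.93 ± 0.24) rose, and the death receptor Fas (-0.60 ± 0.15) fell. Of the 5 epithelial markers, 1 rose, 1 fell and 3 did not pass the test (median 0.07, camera adjusted p = 0.9), and of the 5 endothelial markers, 1 rose, 0 fell and 4 did not pass the test (median -0.10, camera adjusted p = 0.9), with the keratins Krt18 (0.99 ± 0.11) and Krt19 (-0.68 ± 0.20) and with Egfl7 (0.38 ± 0.13) among those called. Camera called 21 of the 34 lists, 11 up and 10 down, of which the cholesterol and glycolysis lists passed with an estimated correlation. Fry called 25.

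IL-1a was compared with vehicle at 4 mM glutamine to ask what the cytokine that induces inflammatory CAFs does with glutamine in supply. Cxcl1 was at 60.5 ± 22.02 TPM (SD, n = 5) with IL-1a and 7.67 ± 1.68 TPM (n = 5) with vehicle, a log2 fold change of 2.77 ± 0.18 (SE; limma adjusted p = 9.4e-09). Ccl2 was at 140.3 ± 32.7 and 48.1 ± 6.68 TPM (1.504 ± 0.21, limma adjusted p = 4.3e-04), and Il6 at 4.26 ± 0.939 and 1.57 ± 0.403 TPM (1.03 ± 0.14, limma adjusted p = 4.3e-04). Acta2 was at 1045 ± 241 and 1262 ± 254 TPM and did not pass the test (-0.28 ± 0.21, limma adjusted p = 0.999). In mm10, Cxcl1 (ENSMUSG00000029380) lies on the plus strand of chromosome 5 from 90891241 to 90893115, and Ccl2 (ENSMUSG00000035385) on the plus strand of chromosome 11 from 82035571 to 82037453.

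Limma called 35 of 12350 genes, 32 higher and 3 lower with IL-1a, with 14 and 1 of them changed at least 2-fold, 744 genes at an unadjusted p under 0.05, and 170 genes without overlap between the groups, where chance gives 0.79%. Only 19 genes were called when the model held these 10 libraries alone, and 88 with a residual component as a covariate, 56 higher and 32 lower. Saa3, an acute-phase protein, rose most (3.34 ± 0.40), at 60.9 TPM in IL-1a replicate 1 and 7.67 to 13.5 TPM in the other 4, and vehicle replicates 1 and 2 were listed at 0. Cxcl5, a chemokine for neutrophils (3.31 ± 0.22), Ccl7 (1.64 ± 0.23), the metalloreductase Steap4 (1.81 ± 0.26) and haptoglobin, Hp (1.63 ± 0.29), followed. Steap4 and Hp did not pass with these 10 libraries alone (adjusted p = 0.11 and 0.15), and they too were highest in IL-1a replicate 1, at 12.6 and 20.5 TPM against 2.29 to 4.93 and 4.04 to 7.12 TPM in the other 4. Of the 3 genes that fell, Cobl, an actin nucleator (-0.55 ± 0.08), met the rule for named genes. The other 2, given after their values were seen, were Ahcyl1 (-0.29 ± 0.06) and C1qtnf3 (-1.15 ± 0.24). Panel genes that did not pass (limma adjusted p of 0.27 to 0.999) were Lif (-0.19 ± 0.16), Cxcl12 (-0.12 ± 0.06), Pdgfra (0.64 ± 0.18), Tagln (-0.32 ± 0.22), Col1a1 (-0.11 ± 0.11), Postn (-0.15 ± 0.12), Asns (-0.04 ± 0.10) and Dusp6 (-0.11 ± 0.17).

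The lists that passed with either correlation were inflammatory. Of the 23 iCAF markers, 6 rose, 0 fell and 17 did not pass the test (10 rose and 0 fell adjusted over the list alone) (median 0.32, camera adjusted p = 1.4e-16, also past with an estimated correlation, adjusted p = 0.0012). Of these markers, Dcn and C3 were high in the libraries that the third component set apart. C3 was at 48.4 and 19.05 TPM in IL-1a replicates 1 and 5, against 9.65 to 13.6 TPM in the other 3. In vehicle replicate 5 it was at 10.3 TPM, against 4.98 to 7.72 in the other 4. Without these 3 libraries the list median was 0.41, and the list passed. Of the 34 NF-kB targets, 9 rose, 0 fell and 25 did not pass the test (17 rose and 0 fell adjusted over the list alone) (median 0.25, camera adjusted p = 1.1e-33, also past with an estimated correlation, adjusted p = 6.2e-05). Members included Nfkbiz (1.10 ± 0.12), Bcl3 (1.09 ± 0.13) and Zc3h12a (1.25 ± 0.14), regulators of the NF-kB response. Of the 14 chemokines, 5 rose, 0 fell and 9 did not pass the test (7 rose and 0 fell adjusted over the list alone) (median 0.51, camera adjusted p = 2.2e-19, also past with an estimated correlation, adjusted p = 8.9e-04), with Cxcl16 at 0.56 ± 0.11. Of the 21 JAK-STAT3 targets, 5 rose, 0 fell and 16 did not pass the test (10 rose and 0 fell adjusted over the list alone) (median 0.27, camera adjusted p = 1.7e-19, also past with an estimated correlation, adjusted p = 0.023). Members included Cebpd, a transcription factor (1.45 ± 0.15). The iCAF score was 5.28 ± 0.21 with IL-1a and 4.53 ± 0.05 with vehicle, a difference of 0.75 (exact permutation p = 0.0079, the smallest possible). It was highest in IL-1a replicate 1 (5.62), without which the difference was 0.66 (exact permutation p = 0.0079). The myCAF score was 5.77 ± 0.04 and 5.87 ± 0.07, a difference of -0.10 (exact permutation p = 0.032, adjusted over 6 scores p = 0.032). That difference did not pass under median-of-ratios scaling (-0.11, exact permutation p = 0.063), nor when IL-1a replicate 1, 2, 3 or 5 or vehicle replicate 1, 2, 3 or 4 was left out (exact permutation p = 0.056 to 0.063).

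In 10 further lists called by camera no member passed over all genes. The IL-1 system list had a median of 0.12 over 12 genes (camera adjusted p = 2.2e-04, and adjusted p = 0.089 with an estimated correlation, and 1 gene rose adjusted over the list alone), and the interferon-stimulated list a median of 0.36 over 30 (camera adjusted p = 6.8e-11, and adjusted p = 0.35 with an estimated correlation), with Usp18 (0.80 ± 0.34) and Gbp3 (0.73 ± 0.28) not past the test. Ribosomal protein genes (40, median 0.05, camera adjusted p = 8.1e-06, and adjusted p = 0.36 with an estimated correlation) and oxidative phosphorylation genes (39, median 0.04, camera adjusted p = 0.0015, and adjusted p = 0.31 with an estimated correlation) had positive medians, and the call of the latter was lost without vehicle replicate 3 (camera adjusted p = 0.073). So did hypoxia genes (23, median 0.06, camera adjusted p = 0.034, and adjusted p = 0.31 with an estimated correlation) and glycolysis genes (21, median 0.06, camera adjusted p = 0.047, and adjusted p = 0.33 with an estimated correlation). Without the filter the calls of the myCAF (0.075) and glycolysis lists (0.072) were lost, the latter also under median-of-ratios scaling (0.068), and with a mean of at least 5 TPM that of the hypoxia list (0.051). The hypoxia call was lost without IL-1a replicate 1 or 3 or vehicle replicate 4 or 5, and the glycolysis call without IL-1a replicate 1, 2, 3 or 4 or vehicle replicate 5 (camera adjusted p = 0.057 to 0.65). YAP and SRF targets (22, median -0.15, camera adjusted p = 4.5e-07, and adjusted p = 0.33 with an estimated correlation) had negative medians, as had myCAF markers (28, -0.10, camera adjusted p = 0.005, and adjusted p = 0.34 with an estimated correlation), collagens (21, -0.07, camera adjusted p = 0.0061, and adjusted p = 0.36 with an estimated correlation) and ATF4 genes (38, -0.05, camera adjusted p = 0.03, and adjusted p = 0.71 with an estimated correlation). The collagen call was lost without IL-1a replicate 3 (camera adjusted p = 0.18). The ATF4 call was lost without IL-1a replicate 1, 2 or 4 or vehicle replicate 5 (0.18 to 0.98), with a median of 0.02 without IL-1a replicate 2 or vehicle replicate 5. It was also lost under quantile normalisation (0.092) and with only the groups compared (0.080). Without the 3 libraries that the third component set apart, the glycolysis (0.12) and hypoxia calls (0.070) were lost. The libraries with the lowest Ccn1, a YAP target, were these 3.

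Among lists that camera did not call, 1 of 8 apCAF markers rose, the antiprotease Slpi (1.60 ± 0.23; camera adjusted p = 0.33), and 1 of 18 angiogenic factors, the growth factor Fgf7 (0.76 ± 0.16; camera adjusted p = 0.6, and 1 rose and 1 fell adjusted over the list alone). Under quantile normalisation, and with the mitochondrially encoded genes left out, 0 angiogenic factors rose. No member passed over all genes in the other 18, except 1 matrix gene that rose under median-of-ratios scaling, 1 that rose under quantile normalisation and 1 that fell with the mitochondrially encoded genes left out. Camera adjusted p was 0.43 for pan-fibroblast genes (median -0.03, mean 0.002), 0.14 for ERK targets, 0.097 for TGF-beta targets, 0.24 for matrix proteins (median -0.06, mean 0.01), 0.24 for aminoacyl-tRNA synthetases and 0.27 for glutamine metabolism. It was 0.53 for cholesterol genes (median -0.02), 0.28 for fatty acid synthesis, 0.43 for lysosome genes, 0.28 for macropinocytosis and exchanger genes, 0.53 for cell cycle genes, whose median changed sign with the scaling, 0.28 for p53 targets, 0.18 for the unfolded protein response and 0.24 for NRF2 genes. It was 0.38, 0.28 and 0.22 for epithelial, endothelial and mesothelial markers and 0.28 for mitochondrially encoded mRNAs. Adjusted over the list alone, 1 pan-fibroblast gene, 1 ERK target, 1 matrix gene and 1 gene of glutamine metabolism rose and 1 matrix gene fell. The TGF-beta list passed with a mean of at least 5 TPM (camera adjusted p = 0.048). Leaving out a single library brought 10 of these 18 past the threshold, the ERK list most strongly (without IL-1a replicate 1 or 5 or vehicle replicate 1 or 2, camera adjusted p = 3.0e-04 to 0.0084). The others were the TGF-beta, matrix, aminoacyl-tRNA synthetase, glutamine, cholesterol, unfolded protein, NRF2, mesothelial and mitochondrially encoded lists, with the library left out among IL-1a replicates 1, 2 and 5 and vehicle replicates 1, 2 and 5 (camera adjusted p = 0.0094 to 0.046). Without the 3 libraries of low Ccn1 the ERK (2.2e-05), unfolded protein and mesothelial lists (both 0.0046) passed. Camera called 14 of the 34 lists, 10 up and 4 down, and fry called 5.

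The vehicle libraries at 0.2 and 4 mM were compared to ask what low glutamine does to the CAFs. Relative to the median gene, Asns, which makes asparagine from glutamine, rose by 1.33 ± 0.10 (SE) on the log2 scale at 0.2 mM, at 616 ± 63.6 TPM (SD, n = 5) against 223 ± 25.8 TPM (n = 5) at 4 mM (limma adjusted p = 5.8e-11). Col1a1 was at 675 ± 82.8 and 3288 ± 269.8 TPM (-2.42 ± 0.11, limma adjusted p = 2.2e-13). Ccl2 was at 3.004 ± 0.759 and 48.1 ± 6.68 TPM (-3.76 ± 0.21, limma adjusted p = 3.4e-12). In mm10, Asns (ENSMUSG00000029752) lies on the minus strand of chromosome 6 from 7675169 to 7693254, and Col1a1 (ENSMUSG00000001506) on the plus strand of chromosome 11 from 94936224 to 94953042.

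Limma called 9055 of 12350 genes, 5606 higher and 3449 lower at 0.2 mM, with 598 and 773 changed at least 2-fold. Under median-of-ratios scaling 4385 were higher and 4438 lower, 49.7% higher against 61.9%. The groups did not overlap in 7392 genes, where chance gives 0.79%. The genes that rose most were Car6, a secreted carbonic anhydrase (4.02 ± 0.24), Avil, an actin-severing protein (3.59 ± 0.20), Gadd45a, a stress sensor (3.405 ± 0.13), Cdsn, an adhesion protein (3.25 ± 0.23), and the stress-induced transcription regulators Nupr1 (2.94 ± 0.10) and Atf3 (2.89 ± 0.14). Among those that fell most, beside Ccl2, were Il33, a cytokine (-4.15 ± 0.22), Lrrn4 (-4.15 ± 0.28), Medag (-4.00 ± 0.19) and C1qtnf1 (-3.72 ± 0.18). The panel genes Il6 (-0.66 ± 0.14), Lif (-0.56 ± 0.16), Cxcl1 (-2.23 ± 0.18), Cxcl12 (-1.44 ± 0.06), Pdgfra (-2.30 ± 0.18), Acta2 (-1.39 ± 0.21), Tagln (-1.25 ± 0.22), Postn (-1.27 ± 0.12) and Dusp6 (-0.58 ± 0.17) fell. The call of Lif was lost without 0.2 mM vehicle replicate 1 or 3 or 4 mM vehicle replicate 2 (limma adjusted p = 0.055 to 0.072), and that of Dusp6 without 0.2 mM vehicle replicate 4 or 4 mM vehicle replicate 1, 2 or 3 (0.052 to 0.086) and without the filter (0.059).

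Most tested members of both subtype lists fell at 0.2 mM. Of the 23 iCAF markers, 2 rose, 20 fell and 1 did not pass the test (median -1.30, camera adjusted p = 2.8e-07, and adjusted p = 0.062 with an estimated correlation). Dcn (-2.15 ± 0.33) and Ccl7 (-3.17 ± 0.23) fell, and Ptgs2, which makes prostaglandins (0.87 ± 0.36), rose. Of the 28 myCAF markers, 3 rose, 20 fell and 5 did not pass the test (3 and 22 under median-of-ratios scaling) (median -1.26, camera adjusted p = 4.2e-07, and adjusted p = 0.062 with an estimated correlation). The collagen receptor Itga11 (-3.28 ± 0.13) and Cthrc1 (-3.01 ± 0.15) fell, and Ccn2 (0.88 ± 0.31) and Inhba (0.83 ± 0.22) rose. The iCAF score was 3.25 ± 0.06 at 0.2 mM and 4.53 ± 0.05 at 4 mM, a difference of -1.28, and the myCAF score 4.77 ± 0.13 and 5.87 ± 0.07, a difference of -1.10 (both exact permutation p = 0.0079, the smallest possible, on the unshifted scale). Of the 12 pan-fibroblast genes, 0 rose, 11 fell and 1 did not pass the test (0 and 12 under median-of-ratios scaling) (median -1.80, camera adjusted p = 6.3e-07, and adjusted p = 0.062 with an estimated correlation). These included S100a4 (-2.78 ± 0.10) and Col1a2 (-2.21 ± 0.16). Of the 8 apCAF markers, 1 rose, 4 fell and 3 did not pass the test (median -0.53, camera adjusted p = 0.12). Cd74, the invariant chain (1.22 ± 0.18), rose, and Slpi (-2.08 ± 0.23) fell, and the list passed with a mean of at least 5 TPM (camera adjusted p = 0.017). Of the 21 collagens, 0 rose, 16 fell and 5 did not pass the test (0 and 18 under median-of-ratios scaling) (median -1.24, camera adjusted p = 3.2e-08, and adjusted p = 0.062 with an estimated correlation). Members included Col8a1 (-2.67 ± 0.21) and Col6a2 (-2.50 ± 0.18). Of the 33 matrix genes, 0 rose, 29 fell and 4 did not pass the test (0 and 30 under median-of-ratios scaling) (median -0.93, camera adjusted p = 5.0e-10, and adjusted p = 0.062 with an estimated correlation). These included Mmp3 (-3.34 ± 0.25), the prolyl hydroxylase P4ha3 (-3.01 ± 0.09) and Tnc (-2.63 ± 0.22). Of the 23 TGF-beta targets, 8 rose, 13 fell and 2 did not pass the test (8 rose and 14 fell adjusted over the list alone, 6 and 14 under median-of-ratios scaling) (median -0.40, camera adjusted p = 0.033, and adjusted p = 0.31 with an estimated correlation). Adam12 (-2.71 ± 0.14) and Tgfb3 (-2.35 ± 0.11) fell. The TGF-beta call was lost under median-of-ratios scaling (camera adjusted p = 0.067). Of the 22 YAP and SRF targets, 7 rose, 10 fell and 5 did not pass the test (5 and 11 under median-of-ratios scaling) (median -0.22, camera adjusted p = 0.093). Vcl, vinculin (-1.20 ± 0.07), fell, and Ajuba (0.78 ± 0.08) rose. The YAP list passed without 4 mM vehicle replicate 5 (camera adjusted p = 0.041).

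**Figure D3:**
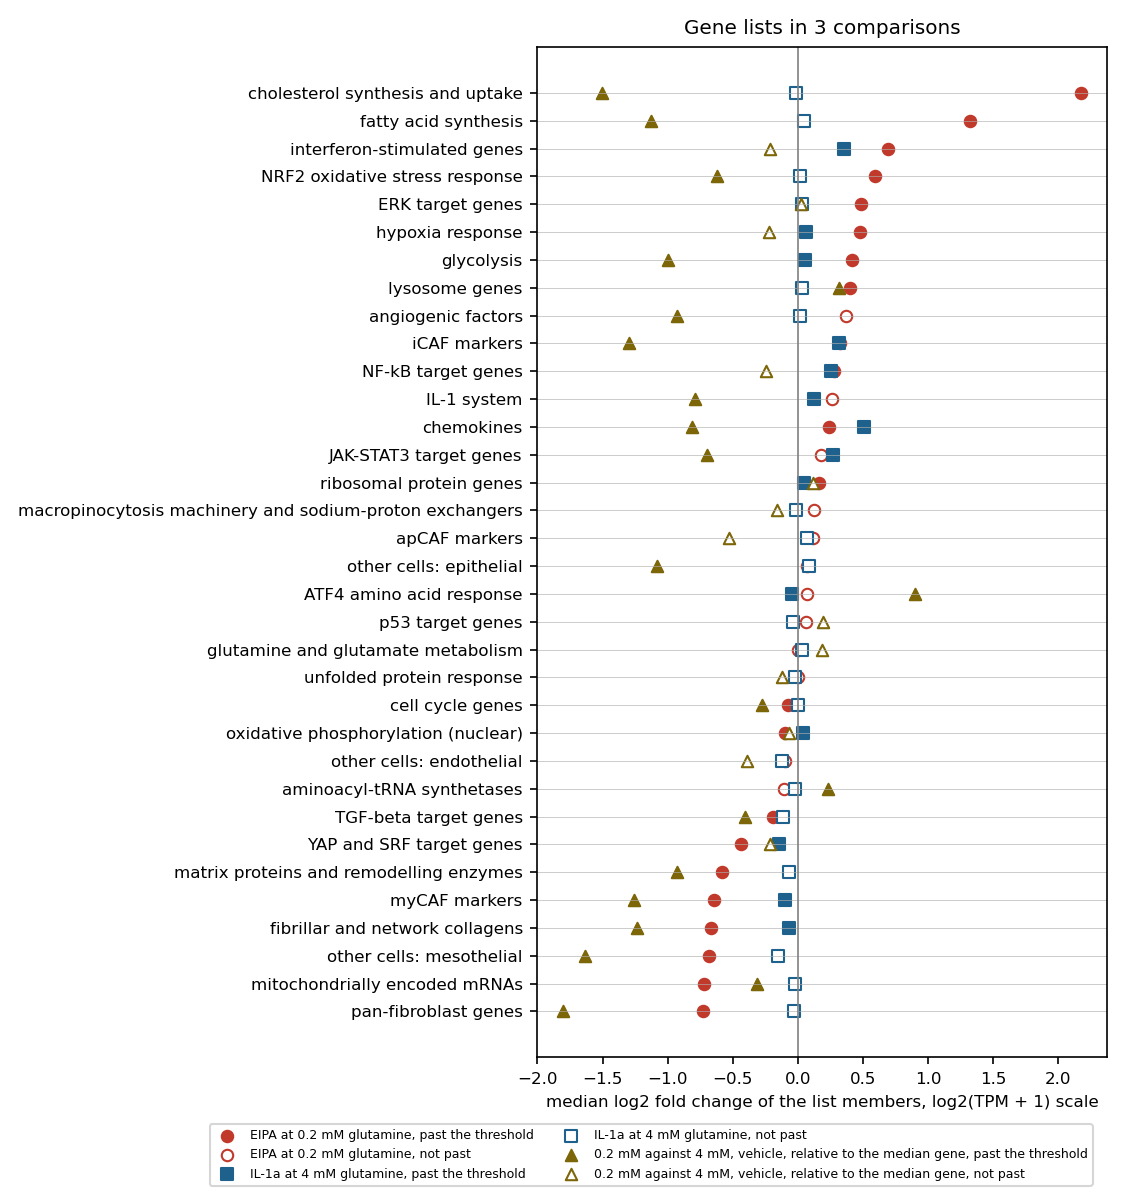
Median log2 fold change of the members of 34 gene lists in 3 comparisons, those between glutamine levels relative to the median gene. Filled symbols mark a camera adjusted p under 0.05 with the preset correlation, and the cholesterol list stood at 2.18 with EIPA and -1.50 at 0.2 mM glutamine.

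At 0.2 mM, of the 38 ATF4 genes, 35 rose, 2 fell and 1 did not pass the test (34 and 2 under median-of-ratios scaling) (median 0.90, camera adjusted p = 2.0e-07, and adjusted p = 0.32 with an estimated correlation). Ppp1r15a (2.85 ± 0.11) and the first of 2 entries named Ddit3 (2.29 ± 0.10) rose, the second being listed at 0 in 1 of the 5 libraries at 0.2 mM, and Ddit4 (-1.18 ± 0.20) and Pck2 (-0.62 ± 0.20) fell. Of the 20 aminoacyl-tRNA synthetases, 13 rose, 1 fell and 6 did not pass the test (11 and 3 under median-of-ratios scaling) (median 0.23, camera adjusted p = 0.019, and adjusted p = 0.31 with an estimated correlation). Members included Nars (1.28 ± 0.11), Wars (1.26 ± 0.09) and Kars (-0.63 ± 0.04). Of the 22 genes of glutamine and glutamate metabolism, 14 rose, 4 fell and 4 did not pass the test (11 and 5 under median-of-ratios scaling) (median 0.18, camera adjusted p = 0.28). Slc7a11 (0.99 ± 0.18) rose, and Gfpt1 of hexosamine synthesis (-0.69 ± 0.08) fell. Of the 20 p53 targets, 12 rose, 4 fell and 4 did not pass the test (10 and 6 under median-of-ratios scaling) (median 0.20, camera adjusted p = 0.37). The cell cycle inhibitor Cdkn1a (2.34 ± 0.16) and Pmaip1 (1.79 ± 0.19) rose, and Sesn1 (-1.39 ± 0.17) fell. Of the 22 genes of the unfolded protein response, 7 rose, 10 fell and 5 did not pass the test (8 rose and 10 fell adjusted over the list alone, 5 and 11 under median-of-ratios scaling) (median -0.12, mean -0.07 and median 0.01 before the shift, camera adjusted p = 0.13). Dnajb9 (1.27 ± 0.13) rose, and Pdia4 (-1.11 ± 0.07) fell. Of the 38 lysosome genes, 27 rose, 6 fell and 5 did not pass the test (22 and 7 under median-of-ratios scaling) (median 0.32, camera adjusted p = 0.0043, and adjusted p = 0.47 with an estimated correlation). Rragd, a GTPase that signals to mTORC1 (2.57 ± 0.11), and Gpnmb (1.15 ± 0.12) rose, and the lipase Lipa (-0.84 ± 0.11) fell. Of the 31 genes of macropinocytosis and exchangers, 8 rose, 14 fell and 9 did not pass the test (6 and 17 under median-of-ratios scaling) (median -0.16, camera adjusted p = 0.08). Wasl (0.83 ± 0.05) rose, and the exchanger regulator Slc9a3r1 (-2.11 ± 0.10) fell. The list passed under median-of-ratios scaling and with a mean of at least 5 TPM (both camera adjusted p = 0.044). Of the 24 NRF2 genes, 7 rose, 15 fell and 2 did not pass the test (6 and 16 under median-of-ratios scaling) (median -0.62, camera adjusted p = 3.2e-04, and adjusted p = 0.31 with an estimated correlation). Gsta4 (-1.98 ± 0.13) fell, and Hmox1 (0.71 ± 0.13) rose.

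At 0.2 mM, of the 26 cholesterol genes, 1 rose, 25 fell and 0 did not pass the test (median -1.50, camera adjusted p = 5.3e-15, and adjusted p = 0.11 with an estimated correlation). Insig1 (-2.01 ± 0.10) and Idi1 (-2.24 ± 0.09) fell, and Ggps1 (0.30 ± 0.08) rose. All 15 genes of fatty acid synthesis fell (median -1.13, camera adjusted p = 9.0e-08, and adjusted p = 0.12 with an estimated correlation). These included Scd2 (-3.26 ± 0.18) and the desaturase Fads2 (-2.87 ± 0.20). Of the 21 glycolysis genes, 1 rose, 18 fell and 2 did not pass the test (2 rose and 18 fell adjusted over the list alone) (median -0.996, camera adjusted p = 3.2e-08, also past with an estimated correlation, adjusted p = 0.01). Pfkl (-2.32 ± 0.11) and Slc16a3 (-2.22 ± 0.09) fell, and the enolase Eno2 (0.85 ± 0.11) rose. Of the 23 hypoxia genes, 9 rose, 11 fell and 3 did not pass the test (7 and 12 under median-of-ratios scaling) (median -0.22, camera adjusted p = 0.33). Ndrg1 (1.92 ± 0.13) rose, and Pdk1 (-1.37 ± 0.10) fell. Of the 39 nuclear oxidative phosphorylation genes, 18 rose, 12 fell and 9 did not pass the test (8 and 19 under median-of-ratios scaling) (median -0.07, test direction down, camera adjusted p = 0.74). Members included Ndufv1 (0.48 ± 0.05) and Ndufb8 (-0.64 ± 0.05). Their median was 0.06 before the shift and changed sign with the scaling. Of the 13 mitochondrially encoded mRNAs, which took 8.87% of TPM at 0.2 mM and 10.4% at 4 mM, 2 rose, 7 fell and 4 did not pass the test (0 and 8 under median-of-ratios scaling) (median -0.32, camera adjusted p = 0.039, and adjusted p = 0.53 with an estimated correlation). mt-Nd6 (-1.36 ± 0.09) and mt-Nd1 (-0.72 ± 0.07) fell. That call was lost without 4 mM vehicle replicate 2 (camera adjusted p = 0.055) or 3 (0.076), under quantile normalisation (0.49, where 3 rose and 3 fell) and without the filter (0.066).

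Of the 34 NF-kB targets, 11 rose, 16 fell and 7 did not pass the test (6 and 17 under median-of-ratios scaling) (median -0.25, camera adjusted p = 0.051). Relb (1.35 ± 0.09) rose. This list passed without 0.2 mM vehicle replicate 2 or 5 or 4 mM vehicle replicate 4 or 5 (camera adjusted p = 0.039 to 0.049), with a pseudocount of 0.1 (0.045), with a mean of at least 5 TPM (0.030), with only the groups compared (0.047) and without the 3 libraries that the third component set apart (0.038). Of the 14 chemokines, 4 rose, 7 fell and 3 did not pass the test (3 and 7 under median-of-ratios scaling) (median -0.81, camera adjusted p = 0.018, and adjusted p = 0.31 with an estimated correlation). Cxcl5 (-2.18 ± 0.22) fell, and Ccl25 (0.83 ± 0.10) rose. The chemokine call was lost under median-of-ratios scaling (camera adjusted p = 0.064) and quantile normalisation (0.0504). Of the 21 JAK-STAT3 targets, 5 rose, 12 fell and 4 did not pass the test (5 rose and 13 fell adjusted over the list alone, 4 and 14 under median-of-ratios scaling) (median -0.70, camera adjusted p = 0.018, and adjusted p = 0.47 with an estimated correlation). Socs3 (-1.37 ± 0.13) fell, and Bcl6 (1.22 ± 0.10) rose. Of the 12 genes of the IL-1 system, 4 rose, 8 fell and 0 did not pass the test (2 and 8 under median-of-ratios scaling) (median -0.79, camera adjusted p = 0.034, and adjusted p = 0.31 with an estimated correlation). Casp1 (-1.98 ± 0.15) and the receptor antagonist Il1rn (-1.55 ± 0.35) fell. The IL-1 system call was lost under median-of-ratios scaling (camera adjusted p = 0.063) and without the filter (0.10). Of the 28 ERK targets, 11 rose, 9 fell and 8 did not pass the test (8 and 11 under median-of-ratios scaling) (median 0.03, test direction down, camera adjusted p = 0.81). Dusp4 (1.56 ± 0.19) and Myc (1.48 ± 0.15) rose, and Ccnd1 (-1.17 ± 0.19) fell. Of the 30 interferon-stimulated genes, 3 rose, 9 fell and 18 did not pass the test (3 rose and 8 fell adjusted over the list alone, 3 and 11 under median-of-ratios scaling) (median -0.21, camera adjusted p = 0.13). Rtp4 (-1.36 ± 0.33) fell, and H2-D1 (0.63 ± 0.09) rose. Of the 18 angiogenic factors, 2 rose, 12 fell and 4 did not pass the test (2 and 14 under median-of-ratios scaling) (median -0.93, camera adjusted p = 6.7e-04, and adjusted p = 0.12 with an estimated correlation). Ptn (-3.24 ± 0.32) fell, and Vegfa (0.93 ± 0.13) rose.

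Of the 40 cell cycle genes, 16 rose, 20 fell and 4 did not pass the test (16 rose and 21 fell adjusted over the list alone, 13 and 23 under median-of-ratios scaling) (median -0.27, camera adjusted p = 0.039, and adjusted p = 0.31 with an estimated correlation). The mitotic kinase Plk1 (-2.21 ± 0.06) fell, and the replication factor Cdt1 (0.98 ± 0.06) rose. The cell cycle call was lost under median-of-ratios scaling (camera adjusted p = 0.068), under quantile normalisation (0.066) and without the filter (0.064). Of the 40 ribosomal protein genes, 26 rose, 8 fell and 6 did not pass the test (19 and 11 under median-of-ratios scaling) (median 0.12, camera adjusted p = 0.072). Members included Rpl18 (0.50 ± 0.07) and Rpl13 (-0.60 ± 0.06), and the list passed without 4 mM vehicle replicate 4 (camera adjusted p = 0.044), without the filter (0.011) and under quantile normalisation (5.1e-04). All 5 epithelial markers fell (median -1.09, camera adjusted p = 0.011, and adjusted p = 0.27 with an estimated correlation), Krt18 (-1.32 ± 0.11) among them. Of the 5 endothelial markers, 1 rose, 2 fell and 2 did not pass the test (median -0.39, camera adjusted p = 0.5). Kdr (0.88 ± 0.13) rose. Of the 11 mesothelial markers, 0 rose, 10 fell and 1 did not pass the test (median -1.64, camera adjusted p = 3.2e-05, and adjusted p = 0.3 with an estimated correlation). Upk1b (-1.81 ± 0.15) fell. Camera called 21 of the 34 lists, 3 up and 18 down, and fry 28, and the glycolysis list alone passed with an estimated correlation.

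The EIPA response at 0.2 mM glutamine was set against that of IL-1a at 4 mM, so agent and glutamine level differed. Limma called 3569 of 12350 genes for a difference between the responses, 2017 with the higher value for EIPA and 1552 for IL-1a. The share higher for EIPA, 56.5%, was 50.5% under median-of-ratios scaling, 49.7% under quantile normalisation and 46.5% with the mitochondrially encoded genes left out. The response of Cxcl1 was larger to IL-1a (EIPA minus IL-1a -1.84 ± 0.26, limma adjusted p = 2.7e-05), as were those of Cxcl5 (-2.39 ± 0.32), Saa3 (-2.78 ± 0.57) and Il6 (-1.35 ± 0.20). On the log2 scale the response of Ccl2 was larger to EIPA (1.47 ± 0.29, limma adjusted p = 8.0e-04). Its vehicle level was 3.004 TPM at 0.2 mM and 48.1 TPM at 4 mM glutamine. Ccl7 (-0.25 ± 0.32), Hp (-0.56 ± 0.41), Pdgfra (0.50 ± 0.25) and Asns (-0.08 ± 0.14) did not pass. Acta2 (-2.03 ± 0.29), Tagln (-2.20 ± 0.31), Col1a1 (-1.26 ± 0.15), Postn (-1.07 ± 0.17) and Lif (-0.66 ± 0.22) had lower values for EIPA. Insig1 (3.90 ± 0.15), Dusp6 (0.75 ± 0.25) and Cxcl12 (0.44 ± 0.09) had higher values. Of the 35 genes called with IL-1a, 24 were called with EIPA, 21 in the same direction, and 23 of the 35 differed between the responses. Of the 32 that rose with IL-1a, 19 rose with EIPA (8.77 expected for independent calls) and 3 fell (6.74 expected). Across the 12350 genes, which are not independent replicates, the log2 fold changes had r = 0.22 and rho = 0.19.

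The EIPA response was also set against the low glutamine response, to ask whether EIPA moved genes further the way of glutamine shortage. Insig1 and Ccl2, which fell at 0.2 mM, rose with EIPA, while Acta2 and Col1a1 fell in both comparisons, and the members of 4 lists are plotted in both comparisons. Of the genes lower at 0.2 mM, 1081 rose with EIPA (945 expected for independent calls) and 751 fell further (727 expected). Of those higher at 0.2 mM, 1425 rose further (1536 expected) and 1226 fell (1182 expected). The correlation across genes was r = -0.08 (rho = -0.06). The comparisons share the 0.2 mM vehicle libraries, so their calls are not independent, and no expected counts allowing for this were computed. In simulations without any true change the sharing alone gave a median r of -0.505. That value cannot be set against the observed r, since the simulated genes carried no true change. The covariance was -0.023 in the data and on average -0.0074 in the simulations. With the shared libraries split into 2 and 3, r had a median of -0.057 over 20 splits (-0.107 to -0.011). The covariance then had a median of -0.017 (-0.030 to -0.0034).

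**Figure D4:**
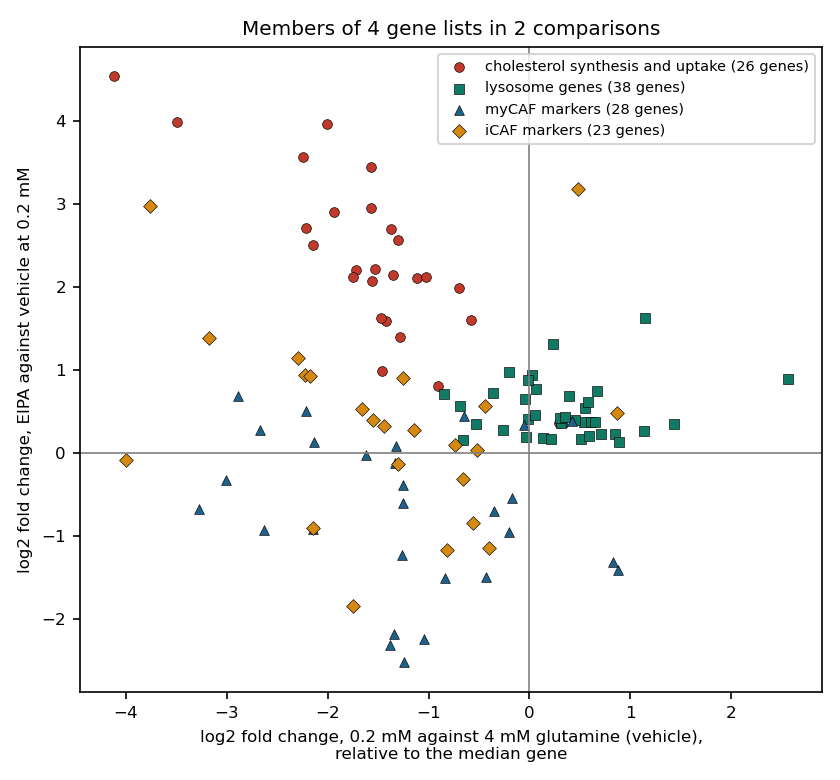
Log2 fold change between 0.2 and 4 mM glutamine in vehicle, relative to the median gene (horizontal), and of EIPA against vehicle at 0.2 mM (vertical), for each tested member of 4 lists, 1 point per gene. All 26 cholesterol genes lay above 0 on the vertical axis, with a median of 2.18.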

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

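The tests of median-of-ratios scaling for both patterns of gene groups, the comparison with nuclear respiratory genes and the SE set against the median of the LXR targets were chosen only after the results were seen.

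Cholesterol genes were low at 0.2 mM glutamine and high with EIPA. The composition of TPM as the whole cause was argued against, since with median-of-ratios scaling the medians were -1.50 between the glutamine levels and 2.14 with EIPA. Unusual 0.2 mM vehicle libraries as the whole cause were argued against as well, since EIPA at 0.2 mM exceeded vehicle at 4 mM by a median of 0.81 (0.63 relative to the median gene), with 23 of 26 genes higher and 1 lower. A change in the sterol level that the cells sense may underlie the pattern and stays open: the median of the 7 tested LXR targets, genes induced by oxysterols, was 0.19 with EIPA and -0.30 between the glutamine levels, relative to the median gene. The latter goes along with the cholesterol genes, by more than the 0.2 named in advance as speaking against this explanation, but passes it by less than the SE over the members (0.20), which went both ways (Nr1h3 0.78 ± 0.21 and Lpcat3 -0.96 ± 0.14). With EIPA they did so too (Lpcat3 0.60 ± 0.14 and Pltp -0.53 ± 0.13). No library combined EIPA with 4 mM glutamine, so whether EIPA raises these genes without glutamine shortage could not be asked.

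The 13 mitochondrially encoded mRNAs were lower with EIPA. TPM composition was argued against by a median of -0.75 with median-of-ratios scaling. A few unusual EIPA libraries were argued against by a gap of 1.77 percentage points between the highest EIPA share (6.78%) and the lowest vehicle share of TPM. A shift common to all transcripts of the respiratory complexes was argued against by the median of the nuclear-encoded members, -0.10 beside -0.72. Fewer mitochondrial genomes, less mitochondrial transcription and a difference in the capture of these transcripts were not tested and are possible explanations that remain.

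A second entry named Ddit3, a stress-induced transcription factor, was listed at 0 in 3 libraries (EIPA replicates 2 and 5 and 0.2 mM vehicle replicate 5) and at 493 to 4839 TPM in the other 17. Lack of expression was argued against, since the first entry was at 580 TPM or more in these 3 libraries. Reads shared between the entries, which overlap by 2925 bases on the plus strand of chromosome 10 (ENSMUSG00000025408 from 127290774 to 127296288 and ENSMUSG00000116429 from 127290829 to 127293753), could be the cause. In 2 of the 3 libraries the first entry was among the highest of its group, and in EIPA replicate 5 it was not, so this stays open. No biological explanation was tested.

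In 15 of 240 groups of 5 libraries (6.25%, where chance gives about 5%), the highest or lowest library lay far from the rest, with a gap to its neighbour of more than 0.71 of the range on the log2 scale. With EIPA, Tagln was lowest in replicate 5 (0.732 of the range), Lif lowest in replicate 1 (0.811), Gla lowest in replicate 5 (0.824) and mt-Nd1 highest in replicate 5 (0.721). Asns (0.730) and Nupr1 (0.844) were lowest in EIPA replicate 4. In 0.2 mM vehicle, Sema3d was highest in replicate 5 (0.733), Asns lowest in replicate 5 (0.783) and Gpnmb lowest in replicate 4 (0.762). With IL-1a, Loxl2 (0.845) and Postn (0.805) were lowest in replicate 3, and Saa3 (0.740) and Il33 (0.793) highest in replicate 1. In 4 mM vehicle, Acta2 was lowest (0.712) and Car6 highest (0.840) in replicate 5.

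Other splits of the same libraries were counted on 100 splits per comparison, the real one included. Fewer than 5 splits of 100 as large was the bound set in advance as speaking against chance. It was met for the genes called with EIPA (1 split, 5986 genes, highest of the others 1869) and at low glutamine (1 split, 9055, 4207). It was also met for the difference between the EIPA and IL-1a responses (2 splits, 3569, 4102) and for the lists called with EIPA (2 splits, 21 lists, 22). In both of these another split called more than the real one, so chance was not excluded. Nor was it excluded for the genes called with IL-1a (5 splits, 35 genes, 1251), for the lists called with IL-1a (24 splits, 14, 21) or for those called at low glutamine (7 splits, 21, 23). The other splits can keep part of a treatment difference, so they do not show what chance alone gives. A split of the 4 mM libraries that called 1251 genes, many times the real count, points to a structure of these samples other than the treatment.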

How the results depend on the processing

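The mitochondrially encoded genes left out, the 3 libraries left out and the residual covariate were chosen after seeing the data. Where no cause is given, the cause was not tested. Requiring an absolute log2 fold change of at least 1 left 389 genes for EIPA, 15 for IL-1a, 1371 for low glutamine and 354 for the difference between responses, fewer by construction. For IL-1a, 19 genes were called with only the groups compared, where fewer libraries inform the variance, and 88 with a residual component as a covariate (56 higher and 32 lower), which removes variance by construction. Without the 3 libraries 34 genes were called, 30 of them among the 35. Lists called with an estimated correlation numbered 2, 4 and 1 for EIPA, IL-1a and low glutamine, and fry called 5 for IL-1a. With a median over the list, the iCAF score under EIPA reversed to -0.27 (exact permutation p = 0.079) and the myCAF score under IL-1a was -0.052 (0.63). The latter was -0.12 with a mean TPM of at least 5 (0.10) and -0.11 under median-of-ratios scaling (0.063). With the replicate number as a block, exact p cannot go below 0.0625, which the scores reached at unchanged values (iCAF 0.33, 0.75 and -1.28, myCAF -0.70, -0.10 and -1.10 for EIPA, IL-1a and low glutamine). The block called 6305, 39 and 9230 genes and 21, 15 and 22 lists for the 3 comparisons, and 4000 genes for the difference. It brought the TGF-beta list with IL-1a (camera adjusted p = 0.040) and the NF-kB list at low glutamine (0.049) past the threshold. Nothing in the labels pairs the replicates. Deviations of libraries of the same number correlated at 0.062 to 0.32 for EIPA and vehicle, -0.28 to 0.60 for IL-1a and vehicle and 0.049 to 0.17 for vehicle at both glutamine levels. Of the 5 libraries of the first group, 4, 2 and 4 correlated best with their own number, a hint from the data and not from the design. Nuclear oxidative phosphorylation genes at low glutamine had a positive direction under fry, reversed from camera (median 0.065, adjusted p = 0.034), since fry does not compare them with other genes. Leaving out each library in turn gave 5424 to 5849 genes and 16 to 21 lists for EIPA, 27 to 47 genes and 11 to 20 lists for IL-1a, 8764 to 8981 genes and 20 to 23 lists for low glutamine, and 3137 to 3759 genes for the difference. Score differences ranged from 0.27 to 0.36 (iCAF) and -0.77 to -0.66 (myCAF) for EIPA, 0.66 to 0.79 and -0.13 to -0.080 for IL-1a, and -1.30 to -1.26 and -1.14 to -1.07 for low glutamine, and r from 0.16 to 0.25 between EIPA and IL-1a and -0.11 to -0.04 between EIPA and low glutamine. Of the named genes' values under the settings other than left-out libraries, 310, 244 and 357 kept their direction and side of the threshold for EIPA, IL-1a and low glutamine, 5, 3 and 5 no longer passed, and 1, 0 and 0 newly passed. For the lists these were 306, 339 and 324, then 26, 27 and 30, then 5, 5 and 16. With a library left out, named genes kept theirs in 319, 210 and 323 values and lists in 325, 305 and 332. Median-of-ratios scaling called 5882, 37 and 8823 genes, 5514, 35 and 7834 of them among the main calls. Unknown depth limits genes of a few TPM, such as Il6 with EIPA, whose change passed with a pseudocount of 0.1 (-0.75, limma adjusted p = 0.022).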

Other observations

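The gene families of the next paragraphs, the comparison of EIPA with vehicle at 4 mM glutamine and their tests were chosen only after the values were seen. Changes between glutamine levels are relative to the median gene.

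All 16 tested circadian clock genes rose at 0.2 mM glutamine, with a median of 0.84 (camera adjusted p = 3.6e-05 over 18 tests, and 0.016 with an estimated correlation). Ciart rose by 2.68 ± 0.16 (SE, n = 5 per group), Cry1 by 1.67 ± 0.07, Cry2 by 1.11 ± 0.08 and Nr1d2 by 1.10 ± 0.11. With EIPA 6 of them rose, among them Ciart (0.89 ± 0.16), and 4 fell, among them Cry1 (-0.30 ± 0.07). Of 40 replication-dependent histone genes, 35 fell and 1 rose at 0.2 mM (median -1.18, camera adjusted p = 3.5e-08, and adjusted p = 0.15 with an estimated correlation). Among those that fell were Hist1h2bc (-2.72 ± 0.10) and Hist1h1c (-2.32 ± 0.11). The libraries were made from polyadenylated RNA, so histone transcripts without a poly(A) tail were not assessed. With EIPA 3 fell and 0 rose. Of 17 host genes of small nucleolar RNAs, 11 rose and 2 fell at 0.2 mM (median 0.72, camera adjusted p = 0.020, and adjusted p = 0.43 with an estimated correlation), with Snhg12 (2.48 ± 0.08), Snhg1 (2.43 ± 0.07), Zfas1 (2.02 ± 0.08) and Gas5 (1.52 ± 0.07) among them.

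Of 12 matrix metalloproteinase genes, 8 fell and 2 rose at 0.2 mM (median -1.23, camera adjusted p = 0.0035, and adjusted p = 0.43 with an estimated correlation), while 5 rose and 4 fell with EIPA, with a median near 0 that changed sign with the scaling. Of 16 subunits of the V-ATPase, the proton pump of lysosomes, 13 rose and 2 fell at 0.2 mM (median 0.51, camera adjusted p = 0.0052, and adjusted p = 0.43 with an estimated correlation). With EIPA 8 of them rose further or newly and 1 fell (median 0.21, camera adjusted p = 0.012, and adjusted p = 0.48 with an estimated correlation), such as Atp6v1h, at 0.71 ± 0.09 and then 0.23 ± 0.09.

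EIPA at 0.2 mM was also compared with vehicle at 4 mM glutamine, where limma called 9475 of 12350 genes and the median gene was higher by 0.18. Relative to the median gene, myCAF markers (median -1.93, 2 of 28 higher and 23 lower, camera adjusted p = 0.044 with an estimated correlation), collagens (-1.95, 1 of 21 higher and 20 lower, 0.044) and iCAF markers (-1.20, 2 of 23 higher and 19 lower, 0.061) lay below vehicle at 4 mM, and so did mesothelial markers (-2.65, 0 of 11 higher and 9 lower, 0.26). Lysosome genes (0.78, 34 of 38 higher and 1 lower, 0.26) and ATF4 genes (0.79, 34 of 38 higher and 0 lower, 0.49) lay above it.

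Within the groups at 4 mM, the first component held 43.1% of the variance between replicates, with scores of 0.45 and 0.39 for IL-1a replicates 1 and 5 and 0.51 for vehicle replicate 5. In 4 mM vehicle replicate 3, mt-Atp8 was at 43606 TPM.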
